A study of Drosophila melanogaster with 18 samples.

How the data were processed

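RNA levels were measured with Affymetrix Drosophila Genome 2.0 arrays, which carry short oligonucleotide probes grouped into probe sets, in 18 samples of ovary RNA from Drosophila melanogaster females. Per the labels' protocols, flies were reared at 20 or 25 °C, total RNA was purified on QIAGEN RNeasy columns, and biotin-labelled target was hybridised, 1 sample to an array. The design text states that the 3 samples of a group were biologically independent. The deposited values are log2 expression values, 1 per probe set and array, made with RMA (background adjustment, normalization across arrays and summary over the probes of a set) per the submitters' processing notes. The software version, the probe set definitions and the annotation used by the authors were not given in the sources used here. RMA brings the arrays to a common distribution, so a change shared by most transcripts could not appear in these values.

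The table held 18952 probe sets. After 183 control probe sets were set aside, 18769 were tested, with no filter on low values. The platform's annotation, with symbols updated through gene identifiers against the NCBI annotation of Drosophila melanogaster Release 6, named 1 gene for 13647 probe sets, several genes for 402 and none for 4720, which are unnamed here. A gene measured by several probe sets was represented by the set with the highest mean over the 18 arrays, which gave 11983 genes, 11894 of them with a position. Because the build behind the array annotation was not given, only chromosome arms and gene order from Release 6 were used.

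Samples were grouped by genotype and temperature as their titles gave them, into 6 groups of 3. The genotype field of RpII2154/FM7 replicates 2 and 3 names FM8 and FM9 instead of FM7, and the titles were followed. The genotypes were yw, Marcal1del/del, RpII2154/FM7 and RpII2154/FM7;Marcal1del/del, and only yw and Marcal1del/del were sampled at 25 °C. The array names fell into 2 series, with the 12 yw and Marcal1del/del arrays in 1 series and the 6 RpII2154/FM7 and RpII2154/FM7;Marcal1del/del arrays in the other. Array series and genotype therefore could not be told apart where RpII2154/FM7 groups were compared with the others. Whether equal replicate numbers marked paired samples was checked from the arrays' deviations from their group means, and they did not.

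Each comparison was fitted with limma (version 3.58.1 in R 4.3.3) on all 18 arrays, with a group term only, moderated variances (residual degrees of freedom 12, prior degrees of freedom 3.85) and 2-sided tests. P-values were adjusted by the Benjamini-Hochberg method within each of 9 contrasts, and a probe set was called at an adjusted p under 0.05. The contrasts were Marcal1del/del against yw at each temperature, 25 against 20 °C in each of these genotypes, the difference between those temperature effects, Marcal1del/del in the RpII2154/FM7 background, the difference between the Marcal1del/del effects with and without RpII2154/FM7, and RpII2154/FM7 against its absence in each Marcal1 genotype.

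Gene lists were fixed before the data were examined, as were the tests, the rule for naming genes and all alternatives except those said to have been chosen later. The 23 lists were heat shock and chaperones, immune effectors, oxidative stress and detoxification, eggshell, yolk, maternal germline, piRNA pathway, replication and DNA repair, cell death, RNA polymerase II and elongation, chromatin remodelling, ribosomal proteins, oxidative phosphorylation, proteasome, ecdysone synthesis and response, muscle, fat body, hemocyte, gut, spermatheca and seminal receptacle, testis and sperm, neuron, and visible markers and engineered loci. Each list's shift was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. The same test with the correlation estimated from the residuals stands beside it. The test fry, which asks whether a list's own genes move, was also run and is quoted for the ecdysone list alone. Members called over all probe sets were counted, and again adjusted over the list alone.

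Named in each comparison were Marcal1, RpII215, w and y whatever their test. To these were added the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap (that condition was not applied to the differences of effects), and up to 4 called members of each list. RpII215 and w had no probe set named for that gene alone here. Positions were tested with Fisher's exact test, 2-sided, for the 200 measured genes on each side of Marcal1 and for the X chromosome against the autosomes.

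In simulated data built on the real probe set means and variances, 200 of 18769 probe sets were changed by known folds. For Marcal1del/del against yw at 20 °C, 47.8% of 1.5-fold, 85.1% of 2-fold and 100% of 4-fold changes were recovered, and 8 of 163 calls (4.91%) were false. For the difference between the Marcal1del/del effects with and without RpII2154/FM7 the recovered shares were 11.9%, 68.7% and 95.5%, and 2 of 119 calls (1.68%) were false. The simulated noise was independent between probe sets. On the real arrays genes deviated together, with a mean within-group r of 0.72 in the eggshell list. These shares therefore hold for the simulated setting and may not hold for the real arrays.

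Alternatives were repeated quantile normalization, cyclic loess, only probe sets above the median, a variance trend with intensity, only the groups compared, only arrays of the same name series, the replicate number as a block, a 1.5-fold minimum, the mean over a gene's probe sets, a window of 50 genes around Marcal1, an estimated correlation in the list test, and each array left out in turn. Leaving out 3 arrays that lay over 1.5 log2 units from the nearest array of their group on the eggshell or muscle list, and comparing chromosome 2 with chromosome 3, were chosen after seeing the data. Calls of single genes were not repeated for the arrays of the same name series or the 1.5-fold minimum. Genes whose probe set was not above the median were not tested with that filter. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.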

Results

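Ovary transcript levels were compared between 4 genotypes, 2 of which were sampled at 2 temperatures. The strain yw served as the control, and Marcal1del/del is homozygous for a deletion in Marcal1, the fly counterpart of human SMARCAL1, an SNF2-family helicase that anneals DNA strands. RpII2154/FM7 females carry an allele of RpII215, the gene of the largest subunit of RNA polymerase II, over the X-chromosome balancer FM7, and RpII2154/FM7;Marcal1del/del combines both. The series title places the study in the question of how environmental and genetic disturbances of gene expression bear on the penetrance of SMARCAL1 mutations, and the labels call 25 °C a heat stress relative to 20 °C. Values are RMA log2 intensities, with 3 arrays per group, so folds are ratios of normalized intensity, and the number of arrays limits the precision. Array medians lay between 4.08 and 4.2. Pearson correlations across probe sets were 0.986 to 0.997 between arrays of a group and 0.981 to 0.995 between groups.

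Some arrays stood apart from their groups on gene sets that follow egg chamber stage or other tissue. The eggshell list, made of chorion and vitelline membrane genes of late follicle cells, averaged 9.69 on yw replicate 1 at 20 °C against 12.18 on both other arrays of that group. On RpII2154/FM7 replicate 3 it averaged 8.64, against 12.45 and 12.58. The muscle list averaged 7.80 on yw replicate 1 at 25 °C against 5.72 and 6. The 3′ minus 5′ difference of the GAPDH control probe sets, a sign of RNA integrity, was 1.49 ± 0.14 (SD, n = 3) in RpII2154/FM7 and 1.53 ± 0.26 in RpII2154/FM7;Marcal1del/del. It was 1.07 to 1.28 on average in the other 4 groups. The same difference for actin was 1.37 ± 0.17 in RpII2154/FM7, 1.7 ± 0.29 in RpII2154/FM7;Marcal1del/del and 0.95 to 1.05 on average elsewhere.

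**Figure D1:**
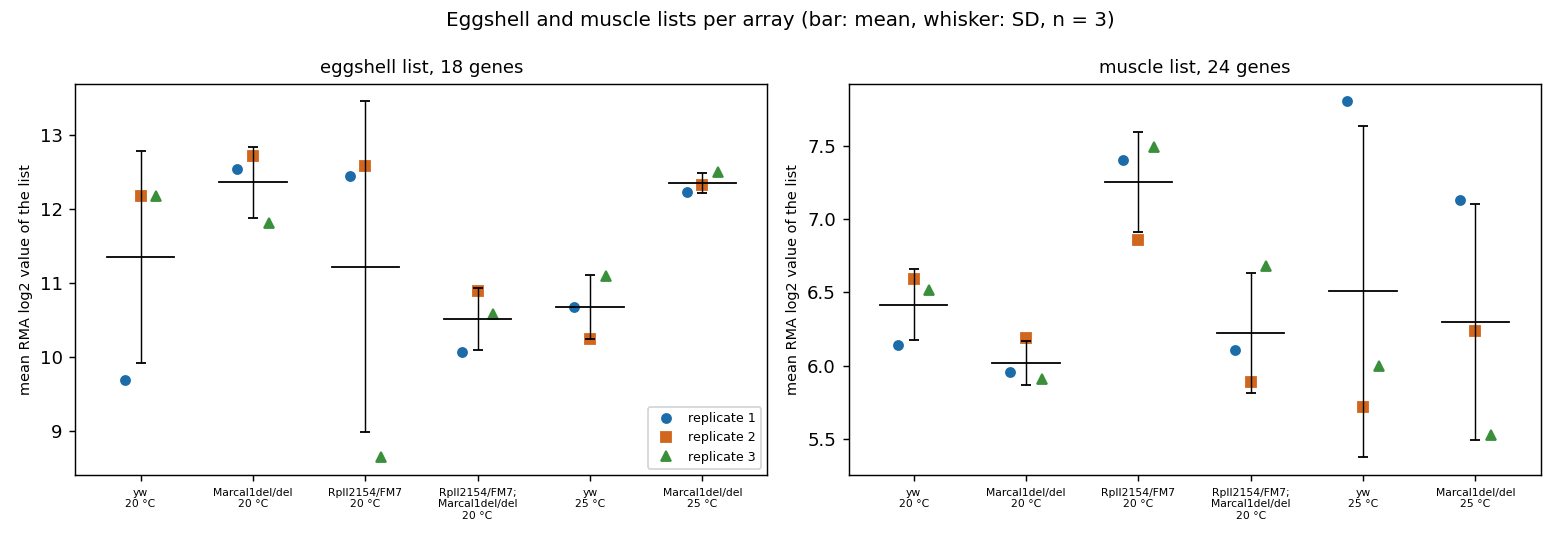
Mean RMA log2 value of the eggshell list (18 genes) and the muscle list (24 genes) on each of the 18 arrays, by group; points are replicates, bars the group mean and whiskers the SD (n = 3). The eggshell values of yw replicate 1 at 20 °C (9.69) and RpII2154/FM7 replicate 3 (8.64), and the muscle value of yw replicate 1 at 25 °C (7.80), lie far from their groups.

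The Marcal1 probe set was lower in every Marcal1del/del group. Its level was 7.94 ± 0.49 (SD, n = 3) in yw and 5.87 ± 0.03 in Marcal1del/del at 20 °C, 8.11 ± 0.24 and 6.03 ± 0.14 at 25 °C, and 7.79 ± 0.21 in RpII2154/FM7 against 5.84 ± 0.38 in RpII2154/FM7;Marcal1del/del. The falls were 4.19-fold (log2 change -2.07 ± 0.22 SE, adjusted p = 4.4e-05), 4.24-fold (-2.08 ± 0.22, adjusted p = 3.7e-05) and 3.88-fold (-1.95 ± 0.22, adjusted p = 8.3e-05). Where the probes lie relative to the deleted part was not given in the sources used here. The level of y, whose mutation marks the yw strain, was 3.14 to 3.43 in all 6 groups, below the median of every array.

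**Figure D2:**
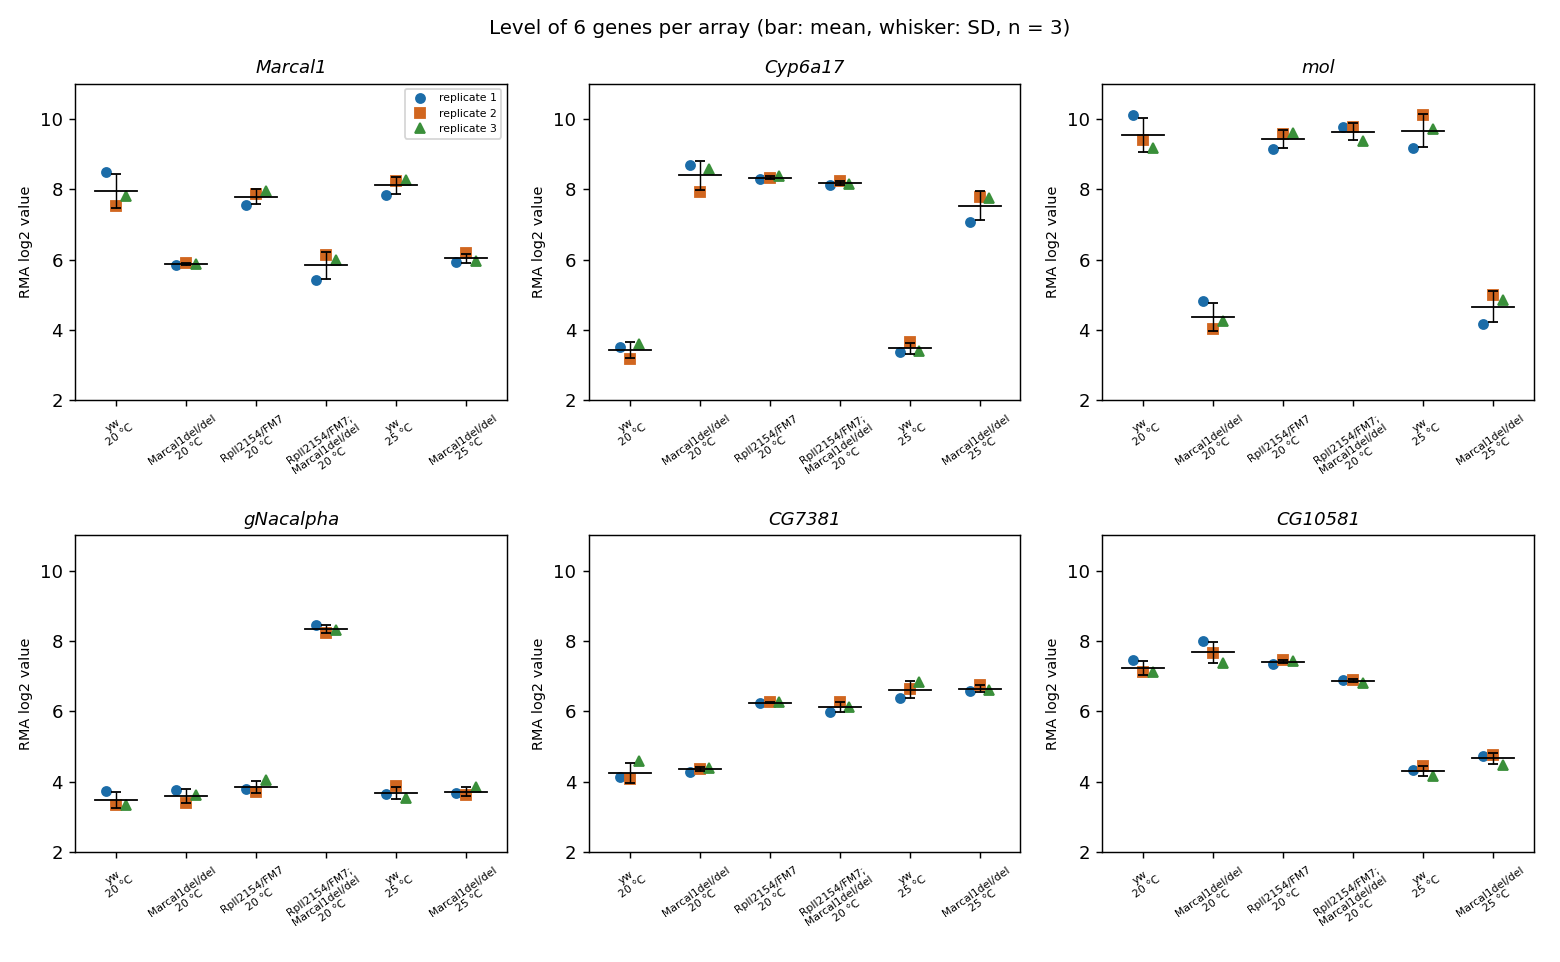
RMA log2 value of 6 genes on each array by group; points are replicates, bars the group mean and whiskers the SD (n = 3). Marcal1 averaged 5.84 to 6.03 in the Marcal1del/del groups and 7.79 to 8.11 in the others, gNacalpha averaged 8.33 in RpII2154/FM7;Marcal1del/del against 3.85 in RpII2154/FM7, and CG7381 and CG10581 moved with temperature in yw and Marcal1del/del.

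Marcal1del/del was first compared with yw at 20 °C. Whether these stocks share a genetic background apart from Marcal1 was not given in the sources used here, so the changes are those between the stocks. Among the largest rises were Cyp6a17, a cytochrome P450 gene (31.1-fold, log2 4.96 ± 0.20 SE, adjusted p = 6.6e-10), and ry, which encodes xanthine dehydrogenase (14.2-fold, 3.83 ± 0.33, adjusted p = 5.5e-06). CG5096 and CG13138 rose 11.3-fold each, CG14502 7.17-fold, CG13532 6.87-fold, CG4676 4.92-fold, CG44153 4.33-fold, jtb 3.94-fold and CG10621 3.78-fold. The gene mol, a maturation factor of the NADPH oxidase Duox, fell 36.5-fold (log2 -5.19 ± 0.29), from 9.55 ± 0.49 to 4.36 ± 0.40 (SD, n = 3). Among the other falls were the noncoding CR44101 (11.5-fold), CG42807 (10.5-fold), the P450 gene Cyp4p2 (9.81-fold), lncRNA:CR32368 (9.06-fold), the ceramidase gene bwa (6.16-fold), the lipocalin gene GLaz (5.80-fold), CG10151 (5.76-fold), CG10013 (5.72-fold) and the mismatch repair gene Pms2 (5.44-fold). For 10 of these 20 genes, Cyp6a17 (3.43 in yw) and ry (3.65 in yw) among them, the lower group lay under every array median (4.08 to 4.2). Such folds, here and below, are lower bounds for the signal of a probe set, and their order means little.

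Of the 18769 probe sets, 99 rose and 122 fell, 221 in all. The calls covered 175 genes, counted here and below only through the probe set that represents a gene. An unadjusted p under 0.05 was found for 1436 probe sets against 938 by chance. The oxidative stress and detoxification list had 3 members up and 3 down among 35 (6 and 6 adjusted over the list alone): Cyp6a17 and Cyp4e2 (log2 1.06 ± 0.11) rose, while Cyp4p1 (-1.34 ± 0.17) and Cyp6a23 (-1.21 ± 0.27) fell. As a whole that list did not shift (mean 0.02, adjusted p = 0.765). The level of Cyp4p1 in Marcal1del/del, 4.06, lay under every array median. Past the threshold were the eggshell list, higher by a mean log2 of 1.02 with 17 of 18 members positive (adjusted p = 0.0126), and the replication and DNA repair list, by 0.14 with 38 of 47 positive (adjusted p = 0.00143). The hemocyte list was lower by a mean log2 of -0.21, with 3 of 15 positive (adjusted p = 0.0354). Each had an adjusted p of 0.919 with an estimated correlation, and none of their members was called over all genes or adjusted over the list alone. In the muscle list TpnC4, a troponin C gene, fell by 1.70 on the log2 scale (1 of 24 called, and 1 adjusted over the list alone). Its level in Marcal1del/del, 2.77, lay under every array median.

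The count of calls at 20 °C was 134 with only these 6 arrays fitted, 142 without yw replicate 2, 127 without yw replicate 3, 144 without Marcal1del/del replicate 3, and 385 without the 3 arrays that stood apart, 195 of them shared in the same direction. CG42807 and lncRNA:CR32368 lost their calls in at least 1 alternative (adjusted p up to 0.20), as did 2 of the 4 list members (up to 0.19). The eggshell call ended without yw replicate 1 (mean 0.19) and without Marcal1del/del replicate 2 (0.84). The replication call ended without yw replicate 2 (0.07) or Marcal1del/del replicate 3 (0.04). The hemocyte call ended without yw replicates 2 (-0.14) or 3 (-0.21) or Marcal1del/del replicates 2 (-0.22) or 3 (-0.12).

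The same genotypes were compared at 25 °C. CG13138 rose 18-fold (log2 4.17 ± 0.43 SE), Cyp6a17 16.6-fold (4.05 ± 0.20), ry 13.7-fold, CG14502 8.86-fold, CG5096 7.22-fold, CG44153 6.67-fold, CG13532 5.67-fold and CG4676 5.50-fold. In addition, otk2, a transmembrane receptor of the off-track family, rose 7.99-fold (3.00 ± 0.10, adjusted p = 6.1e-11) and the transporter gene Mrp5 5.20-fold. The falls included CR44101 (36.7-fold), mol (32.0-fold, -5 ± 0.29), GLaz (8.29-fold), Cyp4p2 (6.65-fold) and CG9380 (6.31-fold). The growth factor gene Pvf2 (6.19-fold), CG17470 (6.08-fold), CG31612 (4.85-fold), Naprt (4.83-fold) and CG2993 (4.74-fold) fell as well. The lower group of 10 of these 20 genes lay under every array median, among them CG13138, Cyp6a17, ry and CR44101. The hemocyte list member srp, a GATA transcription factor, rose 3.99-fold (2.00 ± 0.41, adjusted p = 0.021). It was called over all genes and adjusted over the list alone.

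At 25 °C 230 probe sets passed, 99 higher and 131 lower, covering 186 genes. The eggshell list was higher by a mean log2 of 1.68 with 17 of 18 members positive (adjusted p = 3.97e-07; adjusted p = 0.939 with an estimated correlation), with 0 members called over all genes and 4 adjusted over the list alone. All 3 Marcal1del/del arrays averaged above all 3 yw arrays on it, 12.23 to 12.50 against 10.24 to 11.10 (exact permutation p = 0.1, the smallest that 3 against 3 allows). The ribosomal protein list (mean log2 -0.13, 3 of 35 positive, adjusted p = 0.00233) and the proteasome list (-0.09, 8 of 40 positive, adjusted p = 0.0319) were lower, each with adjusted p = 0.939 with an estimated correlation and no called member. In the detoxification list 2 members rose and 2 fell (4 and 8 adjusted over the list alone), namely Cyp6a17 and Cyp4e2 against Cyp6a23 and Cyp4p1. Cyp4p1 lay at 4.04 in Marcal1del/del, under every array median. The count was 138 without yw replicate 2, 131 without yw replicate 3, 125 without Marcal1del/del replicate 2 and 131 without Marcal1del/del replicate 3. Without the arrays that stood apart it was 366, with 189 higher and 177 lower. The ribosomal protein call ended without yw replicate 1 (-0.10) or Marcal1del/del replicate 1 (-0.11), and the proteasome call without yw replicates 2 (-0.06) or 3 (-0.08) or Marcal1del/del replicate 1 (-0.07). Pvf2 lost its call in at least 1 alternative (adjusted p up to 0.065) and srp likewise (up to 0.11).

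The changes between Marcal1del/del and yw at both temperatures overlapped. Both comparisons are of the same stocks, so any fixed difference between the stocks would recur at each temperature. Called in the same direction at 20 and 25 °C were 138 probe sets, 59 higher and 79 lower, against 0.52 and 0.85 for independent lists, and 0 were called in opposite directions. The log2 changes of all probe sets had r = 0.72 across probe sets, which are not independent replicates, and these comparisons share no array.

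RpII2154/FM7;Marcal1del/del was compared with RpII2154/FM7 at 20 °C, stocks whose shared background was likewise not given. The gene gNacalpha, an alpha subunit of the nascent polypeptide-associated complex, rose 22.4-fold (log2 4.48 ± 0.14 SE, adjusted p = 1.2e-11), the P450 gene Cyp12d1-d 19.2-fold (4.26 ± 0.17) and CG13532 18.9-fold (4.24 ± 0.36). CG13540 rose 6.34-fold, CG14502 6.17-fold, the transcription factor gene Sox102F 3.92-fold, CG32259 3.47-fold, CG17470 3.28-fold, CG18536 3.16-fold and CG42565 3.08-fold. Among the falls was Naprt, nicotinate phosphoribosyltransferase of NAD synthesis (7.18-fold, -2.84 ± 0.19). Others were Ccdc85 (6.37-fold), CG10062 (6.21-fold), the peroxiredoxin gene Prx6c (5.80-fold) and GLaz (5.53-fold). The glutathione transferase gene GstE10 (5.49-fold), CG31955 (4.94-fold), CG11034 (4.31-fold) and the meiotic recombination gene vilya (3.93-fold) fell too. The lower group of 9 of the 20 genes lay under every array median, among them gNacalpha (3.85), Cyp12d1-d (3.22) and CG13532 (3.93). Their folds are lower bounds for the signal of those probe sets. A further probe set, which names both Cyp12d1-d and Cyp12d1-p, rose by 1.73 on the log2 scale, less than the 4.26 given above.

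Of 352 called probe sets, 175 rose and 177 fell, covering 272 genes. The ecdysone synthesis and response list was lower by a mean log2 of -0.34 with 4 of 23 members positive (adjusted p = 5.64e-05). Its adjusted p was 0.113 with an estimated correlation and 0.00588 with fry. The fry results of other lists are not given, so that value does not set this list apart. In it 4 members fell (6 adjusted over the list alone): tai, a coactivator of the ecdysone receptor (-1.06 ± 0.21), nvd and dib, enzymes of ecdysteroid synthesis (-0.85 ± 0.19 and -0.46 ± 0.10), and the kinase gene Eip63E (-0.82 ± 0.13). The replication and DNA repair list was higher by 0.23 with 41 of 47 positive (adjusted p = 5.04e-05; adjusted p = 0.859 with an estimated correlation). Its member Ku80, of DNA end joining, rose by 0.67 ± 0.14 (1 called over all genes, 6 adjusted over the list alone). The RNA polymerase II and elongation list was higher by 0.15 with 46 of 54 positive (adjusted p = 0.0016; adjusted p = 0.866 with an estimated correlation), where MED15 rose by 0.40 ± 0.09 (1 called, and 1 adjusted over the list alone).

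Markers of other cell types moved with these groups, and the actin 3′ minus 5′ difference was 1.7 ± 0.29 (SD, n = 3) in RpII2154/FM7;Marcal1del/del against 1.37 ± 0.17 in RpII2154/FM7. The muscle list was lower by a mean log2 of -1.02 with 2 of 24 positive (adjusted p = 4.67e-06; adjusted p = 0.859 with an estimated correlation; 0 called, and 0 adjusted over the list alone). The hemocyte list was lower by -0.52 with 1 of 15 positive (adjusted p = 5.04e-05, and adjusted p = 0.40 with an estimated correlation). In it the prophenoloxidase gene PPO1 fell by 0.79 to 3.91, under every array median (1 called, 5 adjusted over the list alone). The spermatheca list was lower by -0.70 (adjusted p = 0.0239; adjusted p = 0.859 with an estimated correlation), where hdly fell by 1.52 (1 called, and 1 adjusted over the list alone). The eggshell list had a mean change of -0.71 (adjusted p = 0.0282; adjusted p = 0.866 with an estimated correlation; 0 called, and 0 adjusted over the list alone). That mean was -0.10, -0.03 and -2 without RpII2154/FM7 replicates 1, 2 and 3, and -0.49 without RpII2154/FM7;Marcal1del/del replicate 1, and the call was kept only without replicate 3 among these. The spermatheca call ended without RpII2154/FM7 replicate 1 (-0.16) or RpII2154/FM7;Marcal1del/del replicates 1 (-0.47) or 2 (-0.57).

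Germline genes of this comparison moved both ways. Of 32 maternal germline genes, bam, the switch to germline differentiation (1.08 ± 0.23), and mtrm (0.62 ± 0.13) rose, and vls (-0.81 ± 0.17) and bgcn (-0.61 ± 0.15) fell, 4 in all, and 5 adjusted over the list alone. The lower level of bgcn, 3.72, lay under every array median. Among 27 piRNA genes, the methyltransferase gene Hen1 rose by 1.01 ± 0.21 and the helicase gene armi changed by -0.41 ± 0.09 (2 called, 7 adjusted over the list alone). The immune list members PGRP-LB and pirk, negative regulators of the Imd pathway, fell by 1.00 and 0.58 (2 of 18 called, and 2 adjusted over the list alone). In the detoxification list Cyp12d1-d rose while GstE3 and GstD2 fell (3 of 35 called, 8 adjusted over the list alone). The gut list had 2 of 21 called, and 4 adjusted over the list alone. Jon25Biii fell to 3.64, under every array median, and Jon99Ci was called at 0.34 with both levels, 3.62 and 3.96, under them too. All 20 genes with the largest changes, Cyp12d1-d and Marcal1 among them, kept their calls in every alternative that tested them. None of the 20 called list members outside that group did (adjusted p up to 0.20). The count was 153 with only these 6 arrays, 146 without RpII2154/FM7 replicate 1, 172 and 202 without RpII2154/FM7;Marcal1del/del replicates 1 and 2, and 743 without the array that stood apart and those of the other groups.

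Whether the change with Marcal1del/del at 20 °C differed with RpII2154/FM7 was tested next, in stocks whose shared background was not given. Other differences between the stocks could therefore not be told apart from such a dependence. The difference of log2 changes was the quantity tested. It was positive for mol (5.38 ± 0.40 SE), Cyp12d1-d (4.82 ± 0.24), gNacalpha (4.37 ± 0.20), CG17470 (3.41), CG42565 (3.08), CG13540 (3.02), Cyp4p2 (2.85), CG10013 (2.77), Pms2 (2.77) and CG7695 (2.48). For mol, the level was 9.44 in RpII2154/FM7 and 9.63 in RpII2154/FM7;Marcal1del/del, while it fell from 9.55 to 4.36 between yw and Marcal1del/del. The difference was negative for Cyp6a17 (-5.12 ± 0.28), ry (-4.99 ± 0.47), CG13138 (-4.34 ± 0.61), Prx6c (-3.80), CG5096 (-3.43), CG4676 (-3.33), CG32243 (-2.69), jtb (-2.60), GstE10 (-2.48) and CG10621 (-2.25). Cyp6a17 stood at 8.33 and 8.17 in RpII2154/FM7 and RpII2154/FM7;Marcal1del/del, and at 3.43 and 8.39 in yw and Marcal1del/del. Among list members, bam (1.65 ± 0.32), egl (0.81 ± 0.16) and Cyp4p1 (1.29 ± 0.24) had positive differences, PGRP-LB (-1.42 ± 0.26) and GstD2 (-1.33 ± 0.30) negative ones. For 9 of the 20 named genes at least 1 of the 4 groups lay under every array median. Cyp12d1-d (2.85 to 3.41) and gNacalpha (3.48 to 3.85) did so in all but RpII2154/FM7;Marcal1del/del, and Cyp6a17, ry, CG13138 and CG5096 in yw. So did ry in RpII2154/FM7;Marcal1del/del (3.91), and CG5096 in RpII2154/FM7 (3.92) and RpII2154/FM7;Marcal1del/del (3.99). The sizes and order of the differences of these genes are therefore not exact. The list member Cyp4p1 lay under every array median in Marcal1del/del (4.06). A probe set that names both Cyp12d1-d and Cyp12d1-p was lower in Marcal1del/del than in yw (log2 -1.95). It was higher in RpII2154/FM7;Marcal1del/del than in RpII2154/FM7 (1.73).

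In this test 182 probe sets passed, 100 positive and 82 negative, covering 140 genes, and 2005 had an unadjusted p under 0.05 against 938 by chance. The eggshell list differed by a mean log2 of -1.72 (2 of 18 positive, adjusted p = 0.000422), the muscle list by -0.63 (3 of 24, adjusted p = 0.0462) and the spermatheca list by -0.98 (2 of 13, adjusted p = 0.032). Each had adjusted p = 0.995 with an estimated correlation. No member of the 3 was called over all genes, and 1 spermatheca gene was called adjusted over the list alone. The eggshell call ended without yw replicate 1 (-0.89) or RpII2154/FM7 replicate 1 (-1.11). Over all alternatives of the list test the eggshell mean ran from -3.02 to -0.89. The spermatheca call ended without any of 5 arrays, with -0.44 without RpII2154/FM7 replicate 1 as the smallest mean, and the muscle call without any of 8, with -0.46 without RpII2154/FM7;Marcal1del/del replicate 2. The count was 306 without RpII2154/FM7 replicate 3 and 349 without the 3 arrays that stood apart. CG10621 lost its call in at least 1 alternative (adjusted p up to 0.061), as did 3 of the 5 list members (up to 0.12).

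Across all 3 Marcal1 comparisons, 32 probe sets were called in each. About 2.6 would be called in the third if it were independent of those called in both comparisons without RpII2154/FM7, which are of the same stocks. Of them 20 moved the same way, 7 higher and 13 lower, among them CG13532, CG14502 and CG18536 (higher) and GLaz, Naprt, Ccdc85, CG31955 and CG11034 (lower). The other 12 were called in opposite directions with and without RpII2154/FM7, among them CG4676, CG17470 and CG42565. Between the comparisons at 20 °C with and without RpII2154/FM7, 26 calls had the same and 16 the opposite direction (r = 0.13 across probe sets). For 25 °C without against 20 °C with RpII2154/FM7 the counts were 22 and 15 (r = -0.11).

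Gene position was examined because Marcal1 lies on arm 2L and RpII215 and FM7 are X-linked. Among the 200 measured genes on each side of Marcal1, 4.75% (19 of 400) were called in the RpII2154/FM7 background against 2.18% (250 of 11492) elsewhere (odds ratio 2.24, 95% interval 1.31 to 3.63, Fisher's exact p = 0.0028, adjusted p = 0.0084 over 3 comparisons). The shares were 2% against 1.43% at 20 °C (exact p = 0.29, adjusted p = 0.29) and 2.75% against 1.5% at 25 °C (exact p = 0.059, adjusted p = 0.088). With 50 genes on each side the odds ratio was 3.84 (adjusted p = 0.0057) in the RpII2154/FM7 background. It turned from 1.41 to 0.686 at 20 °C and from 1.86 to 0.644 at 25 °C (adjusted p = 1 in each). Genes of the X were called less often than autosomal genes in the RpII2154/FM7 background, 0.854% (16 of 1873) against 2.53% (253 of 10015), with an odds ratio of 0.332 (0.187 to 0.552, exact p = 1.1e-06, adjusted p = 7.7e-06 over 7 comparisons). They were called more often in RpII2154/FM7;Marcal1del/del against Marcal1del/del, 6.3% against 4.22% (odds ratio 1.52, 1.22 to 1.89, exact p = 0.00014, adjusted p = 0.00049), and in RpII2154/FM7 against yw, 4.16% against 3.05% (1.38, exact p = 0.015, adjusted p = 0.035). The last was 1.26 (adjusted p = 0.075) for genes above the median. The other 4 comparisons did not pass, with odds ratios of 0.661, 0.985, 2.14 and 0.727. Compared after seeing the calls, with p adjusted over 7 comparisons, chromosome 2 held more calls than chromosome 3 in all 3 Marcal1 comparisons, 2.14% against 0.997% (exact p = 3.7e-06, adjusted p = 2.6e-05), 2.12% against 1.18% (exact p = 0.00031, adjusted p = 0.00072) and 3.15% against 1.97% (exact p = 0.00019, adjusted p = 0.00066). The other 4 did not pass, with odds ratios of 0.621 and 0.902 for temperature in yw and Marcal1del/del, and 1.18 and 1.05 for RpII2154/FM7 in yw and Marcal1del/del. Genes are not independent replicates in these tests.

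**Figure D3:**
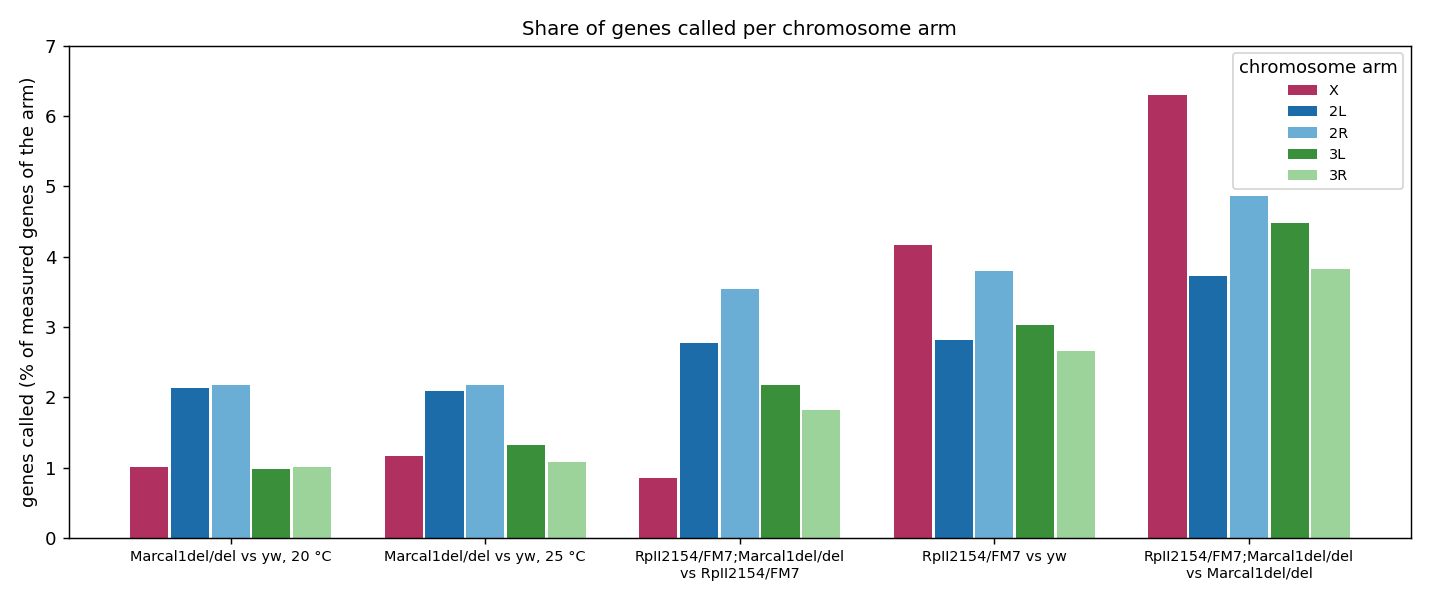
Share of measured genes called (%) on each chromosome arm, for 5 comparisons (3 against 3 arrays each). The X has the lowest bar, 0.854%, in RpII2154/FM7;Marcal1del/del against RpII2154/FM7 and the highest, 6.3%, against Marcal1del/del, and both arms of chromosome 2 stand above both arms of chromosome 3 in the first 3 groups of bars.

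Temperature was compared in yw first. At 25 °C CG7381 rose 5.11-fold (log2 2.35 ± 0.14 SE, adjusted p = 9.4e-08), the glutathione transferase gene GstD9 3.13-fold (1.65 ± 0.21), the cullin gene Cul6 3.07-fold and MCTS1, a translation factor, 2.54-fold (1.35 ± 0.19). CG33062 rose 3.06-fold, CG12520 2.80-fold, CG7800 2.61-fold, jtb 2.37-fold, CG4496 2.30-fold and Taf7, a TFIID subunit, 2.19-fold. CG10581 fell 7.55-fold (-2.92 ± 0.14, adjusted p = 9.6e-09), dao 5.31-fold, the small GTPase gene Rab27 3.79-fold and the transcription factor gene bab1 3.00-fold. Smaller falls of 2.15-fold to 2.67-fold were seen in CG42565, CG32187, CG2812, Hayan, CG10208 and CG13616. The 25 °C levels of bab1 (3.86) and CG13616 (4.01) lay under every array median. Of the 22 heat shock and chaperone genes measured, DnaJ-1, an Hsp40 co-chaperone, was called and rose 1.40-fold (0.49 ± 0.09, adjusted p = 0.028; 1 adjusted over the list alone). The list mean was 0.10 with 17 members positive (adjusted p = 0.114). The Argonaute gene aub of the piRNA pathway rose 1.47-fold (0.55 ± 0.08; 1 of 27 called, 4 adjusted over the list alone).

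In yw 48 probe sets passed, 26 higher and 22 lower. Higher by list were RNA polymerase II and elongation (mean log2 0.15, 44 of 54 positive, adjusted p = 4.54e-05), replication and DNA repair (0.15, 39 of 47, adjusted p = 0.000724) and proteasome (0.12, 35 of 40, adjusted p = 0.0115), while eggshell was lower (-0.67, 2 of 18 positive, adjusted p = 0.0142). Each of the 4 had adjusted p = 0.827 with an estimated correlation. The ecdysone list was lower too (-0.19, 7 of 23, adjusted p = 0.00918; adjusted p = 0.62 with an estimated correlation). None of these members was called over all genes, and 1 ecdysone gene was called adjusted over the list alone. Without yw replicate 2 at 20 °C the calls of RNA polymerase II (0.07), replication (0.09), proteasome (0.06) and eggshell (-0.26) ended. So did eggshell without replicate 3 at 20 °C (-0.26), and eggshell (-0.45), proteasome (0.09) and ecdysone (-0.11) without replicate 2 at 25 °C. Over all alternatives of the list test the eggshell mean ran from -1.51 to -0.26. Only 2 probe sets passed with just these 6 arrays, 31 with the arrays of their series, 23, 27, 24 and 25 without yw replicates 2 and 3 at 20 °C and 2 and 3 at 25 °C, 146 without replicate 1 at 25 °C, and 788 without the arrays that stood apart, 46 of them shared. CG7381 and CG10581 kept their calls in every alternative that tested them. The other 18 of the 20 named genes, with DnaJ-1 and aub, did not (adjusted p up to 0.58).

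In Marcal1del/del, 25 °C raised the adhesion gene rst 5.18-fold (log2 2.37 ± 0.36 SE), CG7381 4.89-fold (2.29 ± 0.14), Asph 4.51-fold, otk2 4.29-fold (2.10 ± 0.10), Pms2 3.97-fold (1.99 ± 0.14) and CG2961 3.78-fold. CG7800 rose 3.47-fold, CG1503 3.06-fold, MCTS1 2.65-fold and pon 2.62-fold. CG10581 fell 8.07-fold (-3.01 ± 0.14, adjusted p = 5.8e-09), CG10208 2.79-fold, CG2187 2.63-fold, and Gbeta5 and Rab27 2.48-fold each, with falls of 1.79-fold to 1.92-fold in CG31517, CG8306, PPO3, TBC1D16 and CG32536. The glutathione transferase gene GstE6 rose by 0.91 ± 0.17 (1 of 35 called, 7 adjusted over the list alone) and aub by 0.62 ± 0.08 (1 of 27, and 1 adjusted over the list alone).

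Here 38 probe sets passed, 25 higher and 13 lower, and 797 had an unadjusted p under 0.05, fewer than the 938 by chance. With limma's camera 0 of the 23 lists passed, at either correlation. The count was 16 with only these arrays, 25 with only the arrays of their series, 15 and 22 without replicates 2 and 3 at 20 °C, 10 and 18 without replicates 2 and 3 at 25 °C, and 64 without the arrays that stood apart. CG7381, otk2, Pms2, CG7800, CG10581 and CG10208 kept their calls in every alternative that tested them. The other 14 named genes did not (adjusted p up to 0.32), nor did GstE6 and aub (up to 0.26).

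Both genotypes shared 18 temperature calls in the same direction, 12 higher and 6 lower, against 0.035 and 0.015 for independent lists, and 0 in the opposite direction (r = 0.47 across probe sets, no array in common). Among them were CG7381, CG7800, MCTS1, CG4496, CG7565, aub and the ubiquitin ligase gene Roc1a (higher), and CG10581, Rab27, CG10208 and CG32536 (lower).

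**Figure D4:**
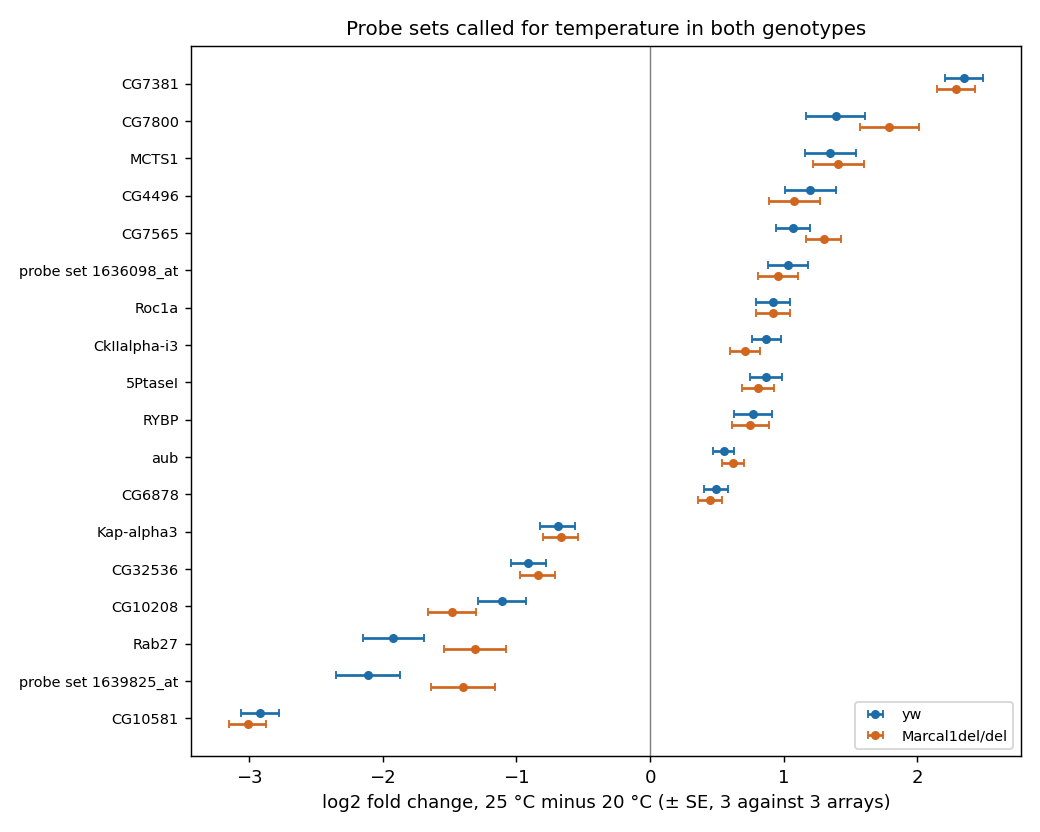
Log2 fold change of 25 against 20 °C (± SE, 3 against 3 arrays) in yw and in Marcal1del/del for the 18 probe sets called in both; the vertical line marks no change. All 18 lie on the same side of 0 in both genotypes, from 2.35 and 2.29 for CG7381 to -2.92 and -3.01 for CG10581.

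The test of the difference between the temperature effects called 2 probe sets. An unadjusted p under 0.05 was found for 295 probe sets, fewer than the 938 by chance. The small count of calls does not show that the temperature response was alike in both genotypes. The log2 change from 20 to 25 °C was more positive in Marcal1del/del than in yw for both called probe sets: otk2 (2.11 ± 0.15 SE, adjusted p = 2.6e-06) and Pms2 (1.82 ± 0.20, adjusted p = 0.001). The level of otk2 was 5.47 and 7.57 at 20 and 25 °C in Marcal1del/del, against 4.59 and 4.57 in yw, and Pms2 was 5.93 and 7.92 against 8.38 and 8.54. Lists that passed were replication and DNA repair (mean -0.18, 6 of 47 positive, adjusted p = 5.32e-06), proteasome (-0.12, adjusted p = 0.000768), eggshell (0.67, adjusted p = 0.0176) and ecdysone (0.18, adjusted p = 0.0131), with RNA polymerase II and elongation at -0.08 (adjusted p = 0.0408). Their adjusted p was 0.719 to 0.802 with an estimated correlation, and 0 members were called, over all genes or adjusted over the list alone. Without Marcal1del/del replicate 3 at 20 °C 0 lists passed. Without yw replicate 2 at 20 °C the eggshell (0.25), proteasome (-0.06) and RNA polymerase II (-0.01) calls ended. So did eggshell (0.25) and RNA polymerase II (-0.08) without yw replicate 3 at 20 °C. Leaving out yw replicate 2 at 25 °C ended the eggshell (0.45), ecdysone (0.10) and RNA polymerase II (-0.04) calls. The ecdysone call also ended without Marcal1del/del replicate 1 at 20 °C (0.15). That of RNA polymerase II also ended without yw replicate 3 (-0.05) or Marcal1del/del replicate 1 (-0.06) at 25 °C. The eggshell mean ran from 0.251 to 1.502 over all alternatives of the list test. In this test 13 probe sets were called without the 3 arrays that stood apart.

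RpII2154/FM7 was compared with yw at 20 °C. Cyp6a17 rose 29.8-fold (log2 4.90 ± 0.20 SE, adjusted p = 7.1e-10), tut, a partner of Bam in the germline, 12.4-fold (3.63 ± 0.44), CG9095 6.54-fold, GstE10 6.02-fold, CG13029 5.09-fold, CG10062 4.88-fold, otk2 4.78-fold, vilya 4.06-fold, CG7381 3.98-fold and CG4250 3.75-fold. The largest falls were CG5953 (9.02-fold, -3.17 ± 0.36), the chitinase gene Cht10 (8.46-fold), Cyp4p2 (6.64-fold), the calcium-binding protein gene Scp1 (6.48-fold), CG7695 (5.28-fold), the receptor gene Ir76a (5.18-fold), FASN3 (4.40-fold), CG42565 (4.10-fold), CG9380 (3.71-fold) and CG10151 (3.59-fold). For Cyp6a17, CG9095, Cht10 and Ir76a the lower group lay under every array median. The GAPDH 3′ minus 5′ difference was 1.49 ± 0.14 (SD, n = 3) against 1.15 ± 0.05 in these groups, and the arrays belong to different series.

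Of 518 called probe sets 285 rose and 233 fell, covering 387 genes. The piRNA pathway list was higher by a mean log2 of 0.22 with 22 of 27 positive (adjusted p = 0.0216; adjusted p = 0.948 with an estimated correlation). In it fs(1)Yb (1.63 ± 0.31), aub (0.74 ± 0.08) and armi (0.46 ± 0.09) rose, 3 over all genes and 4 adjusted over the list alone. The oxidative phosphorylation list was higher by 0.14 with 61 of 78 positive (adjusted p = 3.46e-05; adjusted p = 0.948 with an estimated correlation), where ATPsynCF6 rose and ND-20L fell (2 called, 6 adjusted over the list alone). The muscle list was higher by 0.84 with 23 of 24 positive (adjusted p = 9.64e-05; adjusted p = 0.948 with an estimated correlation; 0 called over all genes, 3 adjusted over the list alone). Its level was 6.86 to 7.49 on the RpII2154/FM7 arrays and 6.14 to 6.59 on the yw arrays.

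Called members of other lists were the negative elongation factor subunit TH1 (0.87 ± 0.16), RpS10a (1.80 ± 0.38), the TNF ligand gene egr (1.00 ± 0.22), bgcn (0.85), Cyp4e2 (0.94), PPO1 (0.79) and ry (1.42), which rose, and Apoltp (-1.65 ± 0.36), stau (-0.69), Cyp4p1 (-1.04) and Cyp6a2 (-0.97), which fell. The testis gene janB was called at -0.42, with levels of 3.37 and 2.96 under every array median. The lower levels of bgcn (3.49), PPO1 (3.92), ry (3.65) and Cyp6a2 (3.37) lay under every array median too. In the detoxification list 5 rose and 2 fell (11 and 3 adjusted over the list alone). Cell death had 1 of 10 called, and 1 adjusted over the list alone. The piRNA call ended without yw replicates 2 (0.13) or 3 (0.18) or RpII2154/FM7 replicate 3 (0.17). The count was 137 with only these 6 arrays, 324 with a 1.5-fold minimum, 837, 199 and 230 without yw replicates 1, 2 and 3, and 283 and 307 without RpII2154/FM7 replicates 1 and 3. Without the arrays that stood apart it was 666, with 320 higher and 346 lower, and 348 shared with the 518. CG13029, CG4250, FASN3, CG9380 and CG10151 lost their calls in at least 1 alternative (adjusted p up to 0.14), as did 15 of the 17 list members (up to 0.26).

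In the Marcal1del/del background the same comparison gave the most calls, and array series and genotype again could not be told apart. RpII2154/FM7;Marcal1del/del against Marcal1del/del at 20 °C raised CG42857 65.2-fold (log2 6.03 ± 0.87 SE), mol 38.7-fold (5.27 ± 0.29), tut 27.3-fold, gNacalpha 26.8-fold (4.74 ± 0.14), Cyp12d1-d 24.8-fold, CG13540 9.80-fold, rst 9.24-fold, CG31612 6.60-fold, RpS10a 6.43-fold and Pms2 6.14-fold. It lowered ry 11.9-fold (-3.57 ± 0.33), Prx6c 11.2-fold, CG5096 9.95-fold, CG15571 9.65-fold, the fat body gene fit 9.13-fold, CG13138 8.54-fold, Cyp6g1 6.72-fold, CHKov1 6.31-fold, CG30334 5.06-fold and CG17108 4.98-fold. The lower group of 8 of these 20 genes lay under every array median, among them CG42857 (3.26), gNacalpha (3.59), Cyp12d1-d (2.85) and ry (3.91), whose folds are lower bounds.

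Here 407 probe sets rose and 315 fell, 722 in all, covering 546 genes. The eggshell list was lower by a mean log2 of -1.84 with 1 of 18 members positive (adjusted p = 2.81e-05; adjusted p = 0.682 with an estimated correlation). The chorion genes Cp36 (-1.91 ± 0.48) and Cp38 (-1.90 ± 0.49) fell, 2 over all genes and 4 adjusted over the list alone, and list means were 10.07 to 10.90 against 11.82 to 12.72 (exact permutation p = 0.1, the smallest possible). The other 4 lists that passed were higher, each with adjusted p = 0.682 with an estimated correlation. Among piRNA pathway genes (0.25, 19 of 27 positive, adjusted p = 0.0239), moon, BoYb and aub rose by 1.12, 1.02 and 0.44 (3 called, 4 adjusted over the list alone). For RNA polymerase II and elongation (0.16, 43 of 54, adjusted p = 0.0105), TH1, spt4 and the polymerase subunit gene Polr2E rose by 0.71, 0.63 and 0.57 (3 called, 4 adjusted over the list alone). In replication and DNA repair (0.17, 35 of 47, adjusted p = 0.022) Ku80, Mcm5 and Mcm3 rose while PolZ1 fell (4 called, 6 adjusted over the list alone). In oxidative phosphorylation (0.13, 67 of 78, adjusted p = 0.00634) UQCR-11 rose (1 called, and 1 adjusted over the list alone). The GAPDH 3′ minus 5′ difference was 1.53 ± 0.26 (SD, n = 3) against 1.28 ± 0.07 in these groups, and that of actin 1.7 ± 0.29 against 1.05 ± 0.15.

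Of other lists, the germline genes bam (0.92), egl (0.68) and mtrm (0.50) rose and vls (-0.66) fell (4 of 32 called, 7 adjusted over the list alone). GstE7 (1.68) and GstE6 (0.99) rose in the detoxification list, where 4 rose and 1 fell (8 and 4 adjusted over the list alone). Also called were Argk1 (0.54), which rose, B-H2 (0.52), whose levels of 2.43 and 2.95 lie under every array median, and srp (-1.97), NimB5 (-0.78), PGRP-LB (-1.28), nvd (-0.92), tai (-0.85) and Jon25Biii (-0.75), which fell. The lower level of Jon25Biii, 3.64, also lay under every array median. The piRNA call ended without Marcal1del/del replicate 2 (0.18) or RpII2154/FM7;Marcal1del/del replicates 2 (0.23) or 3 (0.25). The replication call ended without Marcal1del/del replicates 1 (0.13) or 2 (0.11) or RpII2154/FM7;Marcal1del/del replicate 1 (0.15), and the RNA polymerase II call without Marcal1del/del replicate 2 (0.11). The count was 427 with a 1.5-fold minimum, 437 and 333 without Marcal1del/del replicates 1 and 2, 430, 424 and 465 without RpII2154/FM7;Marcal1del/del replicates 1, 2 and 3, and 1271 without the 3 arrays that stood apart, 714 of them shared. CG15571, fit, Cyp6g1, CHKov1 and CG17108 lost their calls in at least 1 alternative (adjusted p up to 0.21), as did 20 of the 27 list members.

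The comparisons of RpII2154/FM7 with its absence in both Marcal1 backgrounds shared 119 calls in the same direction, 73 higher and 46 lower. Independent lists would share 6.2 and 3.9, and 22 calls had opposite directions (r = 0.29 across probe sets). Both comparisons also set arrays of different name series against each other, so a difference between the series would recur in both. Marcal1 itself was at -0.15 ± 0.22 (adjusted p = 0.78) and -0.04 ± 0.22 (adjusted p = 0.94) in these comparisons.

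With limma's camera, 12 of the 23 lists passed in none of the 9 contrasts. Their lowest adjusted p was 0.114 for heat shock and chaperones, 0.13 for immune effectors, 0.106 for oxidative stress and detoxification, 0.0505 for yolk, 0.159 for maternal germline, 0.654 for cell death, 0.531 for chromatin remodelling, 0.0771 for fat body, 0.351 for gut, 0.196 for testis and sperm, 0.299 for neuron, and 0.407 for visible markers and engineered loci. No list of the 23 passed in any contrast with an estimated correlation, where the lowest adjusted p was 0.113.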

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

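Results in which the difference between Marcal1del/del and its control stock varied with temperature or with RpII2154/FM7 are gathered here. The stocks' shared background was not given, so other differences between stocks could not be told apart from a dependence on RpII2154/FM7. Of the tests below only the splits of arrays were fixed before the results were seen. The difference between the temperature effects in Marcal1del/del and yw had 2 called probe sets, otk2 (2.11) and Pms2 (1.82). Its lists were eggshell (0.67), replication and DNA repair (-0.18), RNA polymerase II and elongation (-0.08), proteasome (-0.12) and ecdysone synthesis and response (0.18).

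The difference between the Marcal1del/del effects with and without RpII2154/FM7 had 182 called probe sets. It was positive for mol (5.38), Cyp12d1-d (4.82), gNacalpha (4.37), CG17470 (3.41), CG42565 (3.08), CG13540 (3.02), Cyp4p2 (2.85), CG10013 (2.77), Pms2 (2.77) and CG7695 (2.48). It was negative for Cyp6a17 (-5.12), ry (-4.99), CG13138 (-4.34), Prx6c (-3.80), CG5096 (-3.43), CG4676 (-3.33), CG32243 (-2.69), jtb (-2.60), GstE10 (-2.48) and CG10621 (-2.25). Its lists were eggshell (-1.72), muscle (-0.63) and spermatheca and seminal receptacle (-0.98).

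All tests of the next 3 patterns were chosen only after the results had been seen. Genes called the same way in all 3 Marcal1 comparisons lay on chromosome 2, 16 of 16 without Marcal1 itself, against 39% of measured genes, and of those called in opposite directions 5 of 7 did (71.4%, exact binomial p = 0.12). Called probe sets without a position were left out. Nop60B and Spn42Da were counted through probe sets that do not represent them. The set that represents Nop60B moved by only -0.13, -0.06 and -0.18. Variants linked to the chromosome 2 that carries the deletion could give the 16 of 16 but stay open, as that share (exact binomial p = 2.8e-07) is the observation that raised them. Loss of Marcal1 acting alike on genes of every chromosome would give a share near 39%. The lower 95% bound of the observed share was 79.4%. That bound comes from the same observation and takes linked genes as independent draws. It speaks only against such an effect as the sole source of this selected set. Strain variants under the probes stay open: of 2 genes with another probe set above the median, 0 had one that moved at least 50% as much in all 3 comparisons.

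Few X-linked genes were called in RpII2154/FM7;Marcal1del/del against RpII2154/FM7. Groups that share their X chromosomes and differ on the autosomes could give the odds ratio of 0.332, which is the observation itself and leaves this open. X-linked genes being harder to call is set against by the odds ratio of 1.52 in RpII2154/FM7;Marcal1del/del against Marcal1del/del. An effect of Marcal1 alike on every chromosome, as the sole source of these calls, is set against by the upper bound of 0.552. That bound comes from the odds ratio of 0.332 itself and takes genes as independent.

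Among the splits of the yw arrays, 1 across the temperatures gave 1185 calls where temperature gave 48. Preparations with different shares of germline and muscle might give this: over 18 arrays, deviations of the piRNA and muscle lists from their group means had r = -0.596 (permutation p = 0.0082, adjusted p = 0.033 over 4 relations, rho = -0.581, permutation p = 0.02). It was -0.452 without the 2 farthest arrays, -0.685 in the 12 arrays of the first name series and 0.147 in the 6 of the other, while eggshell against piRNA had r = -0.6 (permutation p = 0.036, adjusted p = 0.072, rho = -0.546, permutation p = 0.051), -0.39 without 2 arrays, and -0.739 and -0.799 within the series. These relations cannot tell such shares apart from differences in egg chamber stage, which the eggshell list follows. RNA degradation stays open (r = -0.163, permutation p = 0.31, adjusted p = 0.41, rho = -0.257, permutation p = 0.28). A swap of the labels of yw replicate 1 between temperatures is set against by the temperature score, which was higher by 0.93 on the array labelled 25 °C.

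The splits were fixed before the results were seen, but their division into those that mix both pairs of groups and those that keep a group whole was chosen after. Each comparison of 2 groups has only 10 splits, too few for a share under 0.05. Calls numbered 221 in Marcal1del/del against yw at 20 °C (highest other split 4, 1 of 10 splits as high) and 230 at 25 °C (1, 1 of 10). For temperature they numbered 48 in yw (1185, 2 of 10) and 38 in Marcal1del/del (1, 1 of 10). They were 352 in RpII2154/FM7;Marcal1del/del against RpII2154/FM7 (2, 1 of 10), 518 in RpII2154/FM7 against yw (0, 1 of 10) and 722 in RpII2154/FM7;Marcal1del/del against Marcal1del/del (0, 1 of 10). In the same order, lists past the threshold numbered 3 (highest other 12, 10 of 10 as high), 3 (10, 8 of 10), 5 (9, 7 of 10), 0 (9, 10 of 10), 7 (9, 2 of 10), 3 (11, 8 of 10) and 5 (9, 6 of 10).

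The differences of effects had 100 splits each. For temperature, 18 of 100 gave at least the 2 calls (highest 1615), but 11 of these keep a real group whole and so hold a real effect. Of the 75 splits that mix both pairs 6 gave as many, which leaves the origin of the count open, and otk2 and Pms2 kept their calls without any array. At least the 5 lists came in 62 of 100 (highest 14) and in 47 of the 75, so an arbitrary grouping could give the lists. With and without RpII2154/FM7, 3 of 100 gave at least the 182 calls (highest 813), with 0 of 78 among those that mix both pairs. At least the 3 lists came in 78 of 100 (highest 13), so an arbitrary grouping could give the lists. Splits that mix both pairs break up the real differences within each pair, which adds to the spread and lowers their calls. They therefore cannot decide whether the count of 182 is beyond chance.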

How the results depend on the processing

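No result that passed its test changed direction in any alternative, and the cause of the shifts was not tested unless given. With only the groups compared, which leaves fewer arrays for the variance, calls were 134 for Marcal1del/del against yw at 20 °C, 2 for temperature in yw, 16 for temperature in Marcal1del/del, 153 for RpII2154/FM7;Marcal1del/del against RpII2154/FM7 and 137 for RpII2154/FM7 against yw. Within an array-name series they were 31 and 25 for temperature in yw and Marcal1del/del, and 153 for RpII2154/FM7;Marcal1del/del against RpII2154/FM7. With a 1.5-fold minimum, 324 and 427 remained for RpII2154/FM7 against yw and its counterpart in Marcal1del/del.

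Replicate numbers did not mark pairs: 5 of 18 arrays were nearest to an array of the same number. With the number as a block, calls were 196 and 197 for Marcal1del/del at 20 and 25 °C, 39 and 36 for temperature, 294 for RpII2154/FM7;Marcal1del/del against RpII2154/FM7, 403 and 604 for RpII2154/FM7 in yw and in Marcal1del/del, 2 and 166 for the differences of effects, and 9 lists passed in RpII2154/FM7;Marcal1del/del against Marcal1del/del.

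Without the 3 arrays far from their groups, chosen after seeing the data, calls were 385 and 366 for Marcal1del/del at 20 and 25 °C, 788 and 64 for temperature in yw and Marcal1del/del, 743 for RpII2154/FM7;Marcal1del/del against RpII2154/FM7, 666 and 1271 for RpII2154/FM7 in yw and in Marcal1del/del, and 13 and 349 for the differences of effects. Lists were 9 and 1 for temperature, 7 for Marcal1del/del at 25 °C, 5 and 8 for RpII2154/FM7, and 9 for the difference between temperature effects.

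The estimated correlation left 0 lists in every comparison. With probe sets above the median only, 1 list passed for Marcal1del/del at 20 °C and 1 for the difference with RpII2154/FM7, and the X odds ratio for RpII2154/FM7 against yw was 1.26 (adjusted p = 0.075). With 50 genes on each side of Marcal1 the odds ratios were 0.686 and 0.644 for Marcal1del/del at 20 and 25 °C, turned from 1.41 and 1.86, none of which passed, and 3.84 with RpII2154/FM7. With cyclic loess 3 lists passed for the difference between temperature effects, 1 for the difference with RpII2154/FM7 and 1 for RpII2154/FM7 in Marcal1del/del, and the mean over probe sets gave 5 for the difference with RpII2154/FM7.

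With each array left out, calls ranged from 127 to 246 and 125 to 215 for Marcal1del/del at 20 and 25 °C, 23 to 146 and 10 to 32 for temperature, 2 to 2 for their difference, 146 to 362 with RpII2154/FM7, 128 to 306 for that difference, 199 to 837 for RpII2154/FM7 in yw and 333 to 582 in Marcal1del/del. Lists ranged, in that order, from 1 to 4, 2 to 7, 1 to 9, 0 to 4, 0 to 8, 5 to 9, 0 to 8, 2 to 6 and 2 to 9. Of 164 calls of named genes (92 genes, counted once per comparison) 118 held in every alternative that tested them. So did 16 of 81 calls of list members (54 genes). Probe sets near background, such as that of y, can hide changes, which the restriction to those above the median does not mend.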

Other observations

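The temperature score, the signed mean of the 38 probe sets called for temperature in Marcal1del/del, lay between the 20 and 25 °C groups on all 6 arrays with RpII2154/FM7, which were reared at 20 °C. It was -0.03 to 0.06 in RpII2154/FM7 and 0.01 to 0.06 in RpII2154/FM7;Marcal1del/del, against -0.80 to -0.59 in Marcal1del/del and -0.47 to -0.29 in yw at 20 °C and 0.46 to 0.49 in yw at 25 °C. The probe sets were chosen on the Marcal1del/del arrays. CG7381 averaged 6.25 ± 0.02 (SD, n = 3) in RpII2154/FM7 and 6.12 ± 0.14 in RpII2154/FM7;Marcal1del/del, near its 25 °C levels, but CG10581 averaged 7.41 and 6.86, near its 20 °C levels of 7.23 in yw and 7.67 in Marcal1del/del, and CG10208 averaged 8.01 and 8.21, above its 20 °C levels of 7.23 and 7.32 although it fell at 25 °C. Of the 38 probe sets, 28 had the same sign in RpII2154/FM7 against yw, 12 were called the same way and 3 the opposite way. Array series and genotype cannot be told apart here.

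Several genes had levels that were high or low in only some strains. Cyp6a17 averaged 3.43 and 3.48 in yw at 20 and 25 °C and 7.53 to 8.39 elsewhere, mol averaged 4.36 and 4.66 in Marcal1del/del and 9.44 to 9.66 elsewhere, and gNacalpha averaged 8.33 in RpII2154/FM7;Marcal1del/del against 3.85 in RpII2154/FM7 and 3.59 in Marcal1del/del at 20 °C.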
